A study of Mus musculus with 250 samples.

How the data were processed

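Single epidermal cells were sorted from mouse tail skin and sequenced by Smart-Seq2, a full-length single-cell RNA method without molecular identifiers. Per the labels, the 250 cells came from Lrig1CreER/Rosa-TdTomato mice and carried the Lrig1 lineage label and Sca1 (Ly6a) on the surface. This sort was made to enrich for the upper hair follicle. The labels give every cell a time of 8 weeks, and the further time abbreviation beside it is not spelled out there. Cells fell into 3 regions, a control region without memory (84 cells), a distal memory region (81 cells) and the wound bed (85 cells). Each region was in 2 batches, which made 6 sets of cells, each with its own code in the cell titles. These sets are called plates below. Each plate held cells of a single region and batch, so a difference between regions within a batch is also one between plates.

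The deposited table holds a whole-number count of reads per gene and cell for 27003 gene symbols, of which 5495 had no read in any cell. The submitters' processing notes name Salmon 0.13.1, Seurat and R 4.0.3 with the mouse build mm10 (GRCm38), without the role or order of each. How transcript estimates were summed to genes and rounded was not stated. No cell held fewer than 1019 detected genes, and the labels state no filter on cells. All 250 columns matched a label. Gene identifiers and coordinates came from GENCODE M21 (GRCm38), in which 26417 symbols matched a gene name. From the fixed lists, 17 genes had no row in the table and were not analysed here.

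Reads per cell ranged from 3857 to 3119120 (median 49298) and detected genes from 1019 to 6091 (median 1836.5). No doublets were called, no free RNA was subtracted and no deposited cell was left out of the main results. For shares of cells at equal depth, each cell was thinned to 10000 reads, which left out 1 control, 4 distal and 7 wound bed cells with fewer. Shares of cells have exact Clopper-Pearson 95% intervals, and a gene without reads was given a floor of 3 counts. Intervals and floors cover counting error alone, since reads without molecular identifiers are not independent molecules and several cells can come from 1 animal.

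The labels name no animal, so each region counted as 1 sample and no test between regions was run. Counts were summed per plate, the sums were scaled by TMM (edgeR 4.0.16 in R 4.3.3), and normalised read counts (CPM, the usual unit scaled to library size) were computed from them. Each comparison gave a log2 ratio of scaled CPM plus 1 within each batch, so that batch was not mixed with region. A gene was considered when at least 10% of the cells of 1 or more of the compared regions had a read of it, in each batch. It met the size rule when both log2 ratios were at least 1 in size and had the same sign. Counts under the size rule are given beside the number that independent batches would give. In cells simulated from each batch's gene means and variances at the real read totals, without a region difference, 11.9% of unchanged genes met the rule for the distal and control pair, 9.8% for the wound bed and control pair and 11.8% for the distal and wound bed pair. Simulated cells were drawn independently, with a cap on the spread of a gene and no variation between plates. Real plates could therefore give larger shares without a region difference. The variances were taken over all regions of a batch together, so region differences in the real cells could widen the simulated spread and raise these shares. Which of these errors is larger is not known. Genes given a difference in the simulated distal cells were drawn only from those with reads in at least 25% of all cells. Of those given a 4-fold difference, 63% met the rule in the first pair and 59% in the last. Of those given an 8-fold difference, 87% and 90.9% did. Recovery of sparser genes was not simulated.

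Named genes followed a rule fixed before the data were examined, as were the 29 gene lists, the size rule and a set of alternative settings. The rule took up to 12 genes higher and 12 lower per comparison among those meeting the size rule. These also had reads in at least 25% of the cells of the higher region in each batch, and their share of cells and mean log2 value per cell differed in the same direction. Predicted genes, pseudogenes, ribosomal protein genes, mitochondrial transcripts and spike-ins were excluded, and genes were ranked by the smaller of the batch ratios. Ly6a, Lrig1, Gata6 and list members meeting the size rule were eligible as well, with up to 4 members of each list that stood apart. Not every gene that the rule selected is described in the text. A list's median log2 ratio was set against 10000 random lists matched for expression in 20 bins; it stood apart when it lay outside the central 95% in the same direction in both batches. For a gene without reads in a plate, a bound replaced the ratio, and list medians were computed again with such genes at their bound.

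Cells were clustered, after each gene was centred within each batch, with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 15 components, 15 neighbours, resolution 0.8). A cluster was called like a cell type when its mean marker score exceeded 0.3 and at least 3 markers were found in 25% of its cells, thresholds chosen after the data were seen. Cluster sizes were compared between regions only where none of the cluster's 10 leading genes met the size rule for that pair. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

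The alternative settings fixed in advance were total counts or median-of-ratios factors in place of TMM, pseudocounts of 0.5 and 5 CPM, the mean of per-cell CPM, each gene without its highest cell per plate, cells with at least 2000 genes, cells within 3 median absolute deviations, thinned cells, the largest cell class alone, each batch alone, no detection filter, a 1.5-fold size rule and other clusterings. Alternatives added after the data were seen left out cells over 500000 reads, mitochondrial and repeat-like genes, the cluster led by repeat-like genes, cells with over 5% repeat-like reads or the cluster led by Malat1. Others raised the detection filter to 50% or to the detection criteria of the named genes. A further one gave equal weight to the 3 clusters with at least 2 control and 2 wound bed cells in each batch.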

Results

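Gene expression was measured in 250 single epidermal cells of the Lrig1 lineage from mouse tail skin. Lrig1 marks stem cells of the upper hair follicle, and the reporter labels their progeny. The control region gave 28 and 56 cells in batches 1 and 2, the distal memory region 32 and 49, and the wound bed 30 and 55. Summed reads per plate were 4481121 and 4029606 in control, 10671470 and 2888806 in the distal region, and 1751116 and 2898446 in the wound bed. Median genes per cell were 1876.5 in control, 2067 in the distal region and 1662 in the wound bed, or 1183, 1359 and 1213 after thinning to 10000 reads. The series title concerns skin memory held by progenitors away from an injury. The comparisons ask how Lrig1-lineage cells in the wound bed and at a distance from it differed from cells outside the memory region. No animal is named in the labels, so it is not known whether the batches are replicates, and no value below has an error between animals. Pairs of log2 ratios below are batch 1 then batch 2.

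Wound bed cells carried more RNA of the stefin A genes named by rank, and fewer reads of upper hair follicle genes, than control cells. Stefin A proteins inhibit cysteine proteases in stratified epithelium, and no list of the family was scored. Stfa1 was 86.9-fold higher (log2 ratios 7.54 and 5.34), with reads in 55.3% of wound bed cells (interval 44.1 to 66.1%) and 6.0% of control cells (2.0 to 13.3%). Stfa3 (4.78 and 4.72), Cstdc5 (6.55 and 4.71) and Csta1 (3.0 and 3.76) of the same family were higher too. Reads shared among these close paralogs were not separated here. Equal weight was also given to the 3 clusters with at least 2 cells of both regions in each batch. These held 23 of 85 wound bed cells, and none of them was suprabasal-like. Csta1 then stood at only 0.78 and 0.75 and Cstdc5 at 5.66 and 1.73. Stfa1 was then at 3.97 and 3.71, and Stfa3 at 3.29 and 2.48. At clustering resolution 0.5, Stfa1 and Cstdc5 were among the leading genes of a cluster with a suprabasal marker score of 1.236. Lrig1 itself had reads in 1 of 85 wound bed cells and 18 of 84 control cells. In batch 2 none of 55 wound bed cells had a Lrig1 read. By the floor of 3 counts this allows a share of cells with a read of up to 5.45%, and the gene was at least 22.7-fold lower; in batch 1 a single wound bed read against 24 in control made it 12.3-fold lower (counting interval 2.01 to 506).

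The upper hair follicle list was lower in the wound bed, with medians of -2.38 and -1.38 that lay at percentiles 0.0 and 0.0 of random lists. Of its 12 members considered, 11 were lower in both batches. Those meeting the size rule included Lrig1, Krt79 (-2.30 and -2.02), a keratin of the follicle's upper duct, Cst6 (-2.43 and -1.27), Sostdc1 (-1.74 and -2.11), a secreted inhibitor of BMP and Wnt signals, and Fst (-4.08 and -1.16), which binds activin. Cst6 stood at -0.54 and -0.31, Sostdc1 at -0.82 and -2.21 and Fst at -2.59 and -0.94 with every cell weighted equally, so that none of these met the rule. Within the basal epidermis-like class neither they nor Lrig1 and Krt79 (-4.95 and 2.99) met it, and Lrig1 and Fst did not without the repeat-led cluster. Placing Lrig1 at its bound left both list medians as they were. Gata6, a transcription factor of the follicle's duct cells, was at -0.68 and -1.50. The suprabasal list was higher, with medians of 0.94 and 0.86 at percentiles 99.4 and 98.9, and 6 of its 10 members were higher in both batches. Mt4 (3.60 and 1.61), a metallothionein of differentiating epithelium, and Dsg1a (1.36 and 1.54), a desmosomal cadherin, met the size rule, although Mt4 (-0.49 and 4.91) did not within the basal epidermis-like class, nor Dsg1a in cells with at least 2000 genes (0.32 and 1.19) or without the repeat-led cluster (0.73 in batch 1). Krtdap (1.40 and 0.98) and Krt10 (1.08 and 0.87) were higher without meeting it. Calml3 (-2.82 and -1.04), a calmodulin-like protein, was lower, and at -1.41 and -0.92 with every cell weighted equally. The suprabasal list no longer stood apart in cells with at least 2000 genes, within the basal epidermis-like class, without the repeat-led cluster or without the control cells rich in repeat-like reads. With every cell weighted equally (medians 0.79 and 1.25) it lay at the edge of the random lists, outside it in one draw of them and inside it in another.

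Among the other genes named by rank, Maf (3.01 and 4.58) and Rora (4.2 and 3.26), both transcription factors, were 13.9-fold and 13.3-fold higher in the wound bed. Maf had reads in 80% of wound bed cells and 29.8% of control cells. Psat1 (4.0 and 3.0), an enzyme of serine synthesis, was 11.3-fold higher. Ndufa4l2, a mitochondrial protein induced in hypoxia, was at least 77.4-fold higher in batch 1 and at 2.96 in batch 2, and Smim15 was at 2.92 and 2.67. Ly6c1 had 521 reads in the wound bed against 1 in control in batch 2, a 786-fold difference (141 to 31100), and a log2 ratio of 4.96 in batch 1. Popdc3 and Tent5a also had a single control read in batch 1, with 236-fold (41.6 to 9400) and 618-fold (110 to 24500) differences, and had log2 ratios of 4.49 and 3.17 in batch 2.

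The 12 genes ranked as lower included 3 glutathione transferases of the mu class, which join glutathione to reactive compounds. Gstm1 (-3.59 and -3.91) had reads in 72.6% of control and 27.1% of wound bed cells, Gstm5 (-4.29 and -3.06) in 84.5% and 31.8%, and Gstm2 stood at -2.77 and -3.05. Fzd7 (-3.71 and -3.70), a Wnt receptor, was 13-fold lower, with reads in 56% of control cells (44.7 to 66.8%) and 10.6% of wound bed cells (5.0 to 19.2%). Ahr (-3.93 and -2.61), a receptor for aryl hydrocarbons, and Lmo1 (-2.89 and -4.75), a LIM-domain transcription cofactor, were 9.65-fold and 14.1-fold lower. Marcks (-3.93 and -3.29), Clca3a2 (-5.05 and -3.56), Rab32 (-4.29 and -4.47), Cwh43 (-3.31 and -3.98), Plaa (-5.46 and -2.82) and Adgrl2 (-2.56 and -3.83) completed the set. With every cell weighted equally Ahr stood at -3.88 and -0.27, and without the cells rich in repeat-like reads Plaa was at -0.89 and -2.43 and Rab32 at 0.54 and -4.38, so that they no longer met the rule. Stfa1 lies on chromosome 16 at 36276951 to 36285373, Fzd7 on chromosome 1 at 59482424 to 59486955 and Lrig1 on chromosome 6 at 94604529 to 94700158 (GRCm38).

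Ly6a, which encodes the Sca1 surface protein used for the sort, was itself higher in the wound bed (1.81 and 1.94), with reads in 75.3% of its cells and 32.1% of control cells; it fell short of the size rule in cells with at least 2000 genes (0.66 and 1.67) and within the basal epidermis-like class (0.79 and 1.66). Repeat-like predicted genes took over 5% of non-mitochondrial reads in 18 of 28 and 6 of 56 control cells, against 0 of 30 and 1 of 55 wound bed cells.

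**Figure D1:**
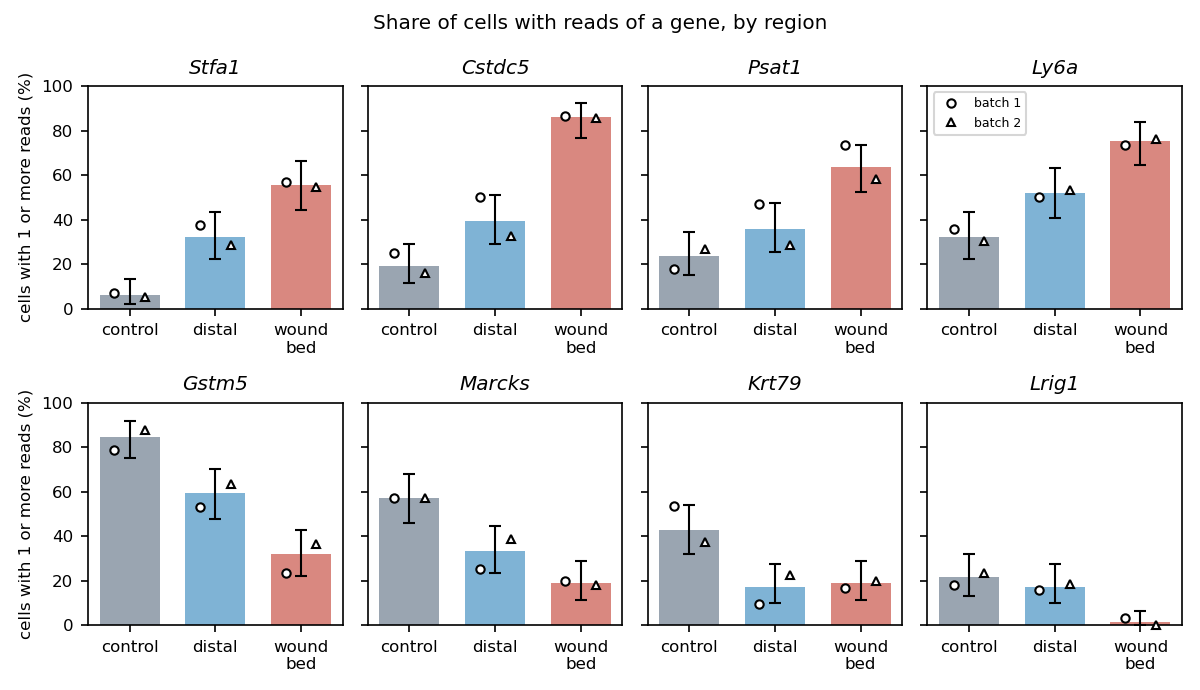
The share of cells with 1 or more reads of 8 genes (vertical axis, percent) is drawn for each region, with bars for all cells, exact 95% intervals as error bars, and circles and triangles for batches 1 and 2. Stfa1 went from 6.0% of control cells to 32.1% of distal and 55.3% of wound bed cells, and Gstm5 from 84.5% to 59.3% and 31.8%, while the share for Krt79, the scaled CPM of Ly6a in batch 1 and that of Lrig1 in batch 2 did not place the distal region between the others.

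By the size rule, 452 genes were higher and 476 lower in the wound bed of 5776 considered, where independent batches would give 347.8 and 374.3, and 675 met the size in opposite directions (723.7 by independence). In simulated cells without a region difference, 638 of 6526 genes met the rule. Across genes, which are not independent replicates, the ratios of the batches had Pearson r 0.15 and Spearman rho 0.12. Of the genes meeting the rule 48.7% were higher, which became 53.1% with total counts in place of TMM and 59.2% of 1145 genes without the cells rich in repeat-like reads. With the detection criteria of the named genes, an alternative added after the data were seen, 83 were higher and 83 lower against 36.3 and 32.7 by independence, and 60 met them in opposite directions (70.7).

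Distal memory cells carried more reads of the stefin A genes Stfa1 and Stfa3, and fewer reads of upper hair follicle genes, than control cells. They also carried more Malat1, a long non-coding RNA kept in the nucleus. The control cells are those of the wound bed comparison, so part of the likeness between the comparisons follows from them. With distal ratios from batch 1 and wound bed ratios from batch 2, which share no cells, 453 genes were at least 2-fold higher and 423 lower in both (351.2 and 343.3 by independence), and with the batches exchanged 262 and 400 (228.7 and 362.3). Stfa1 was 44.9-fold higher (6.53 and 4.45), with reads in 32.1% of distal cells (22.2 to 43.4%), and Stfa3 was 23.8-fold higher (5.94 and 3.20). Malat1 was 19-fold higher (4.55 and 3.94), with reads in 76.5% of distal cells (65.8 to 85.2%) and 51.2% of control cells (40 to 62.3%); it lies on chromosome 19 at 5795690 to 5802672. Without the 4 deepest distal cells, Malat1 stood at 2.5 in batch 1. The upper hair follicle list was lower, with medians of -1.83 and -1.28 at percentiles 0.0 and 0.1 of random lists. Of its members, 9 of 13 were lower in both batches and 1 higher. With every cell weighted equally its medians were -0.73 and -1.07, and it did not stand apart there or in other settings given below. Members meeting the size rule included Cst6 (-3.36 and -2.34), a cystatin, Defb6 (-2.21 and -2.27), a beta-defensin, Plet1 (-2.28 and -1.50) and Krt17 (-1.83 and -1.29). Krt17 fell short of the rule with every cell weighted equally (-0.68 and -0.89), without the 4 deepest cells (-0.5 in batch 1) and in thinned cells (-0.43 and -0.84), and Plet1 was at 3.02 and -1.27 without the repeat-rich cells.

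For distal against control cells, the ratios of the lineage and sort genes had opposite signs in the batches. Lrig1 stood at -1.15 and 0.45, Gata6 at 2.23 and -1.59, and Ly6a at -0.59 and 0.33. Among other genes named by rank, Tnfrsf19, a receptor of the TNF family, had 2 control reads in batch 1 (699-fold higher in distal cells, interval 193 to 5780) and a log2 ratio of 3.13 in batch 2, with reads in 35.8% of distal and 8.3% of control cells. Lrp4, a receptor that binds Wnt inhibitors, had 3 control reads in batch 1 (750-fold, 257 to 3640) and a log2 ratio of 3.44 in batch 2. Fcgbp had 3 control reads in batch 1 (55.5-fold, 18.8 to 270) and Nxf1, an mRNA export factor, and Gga2 had 1 each (84.4-fold, 15 to 3350, and 21.4-fold, 3.66 to 865), with log2 ratios of 3.34, 2.61 and 3.09 in batch 2. Shtn1 (3.50 and 3.70), Tnpo1 (4.42 and 2.93), Mettl7a1 (4.31 and 2.74) and Afap1 (2.54 and 3.03) were higher as well. Other lower genes were Calml3 (-2.58 and -2.27), Slc40a1 (-2.21 and -2.34), the cell's iron exporter, Glul (-1.72 and -2.55), which makes glutamine, Ywhag (-3.92 and -3.05), Plaa (-3.53 and -2.67), Erlec1 (-2.25 and -4.35), Zfand6 (-2.48 and -2.13), Rab32 (-1.78 and -4.37) and Snord17 (-2.11 and -1.65). Without the 4 cells over 500000 reads, batch 1 fell short of the size rule for Shtn1 (0.91), Glul (-0.39) and Rab32 (-0.98), and without the repeat-rich cells Plaa, Erlec1, Ywhag and Rab32 no longer met it.

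In the inflammatory signalling list, Nfkbiz (1.25 and 2.58), a regulator of NF-kappaB targets, and Il1r2 (1.76 and 1.54), the interleukin-1 decoy receptor, met the size rule in distal cells. That list's medians of 1.76 and 1.11 lay at percentiles 89.1 and 95.8 over 5 members, so it did not stand apart. With every cell weighted equally its medians of 2.98 and 1.46 lay at percentiles 99.5 and 99.2, where it did, while Nfkbiz (0.69 and 2.07) no longer met the rule. Il1r2 also met the rule in wound bed cells (3.21 and 1.98), with Il33 (1.06 and 2.35; -0.01 and 2.97 with every cell weighted equally), an alarmin cytokine, and the list's medians there were 3.21 and 0.50. The wound keratinocyte list had medians of 0.72 and -0.26 in distal cells and 2.22 and 0.20 in wound bed cells against control, where Serpinb2 (2.02 and 1.55), a protease inhibitor, met the rule beside Stfa1. Its wound bed medians were 1.57 and 1.31 with every cell weighted equally, and it stood apart there.

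**Figure D2:**
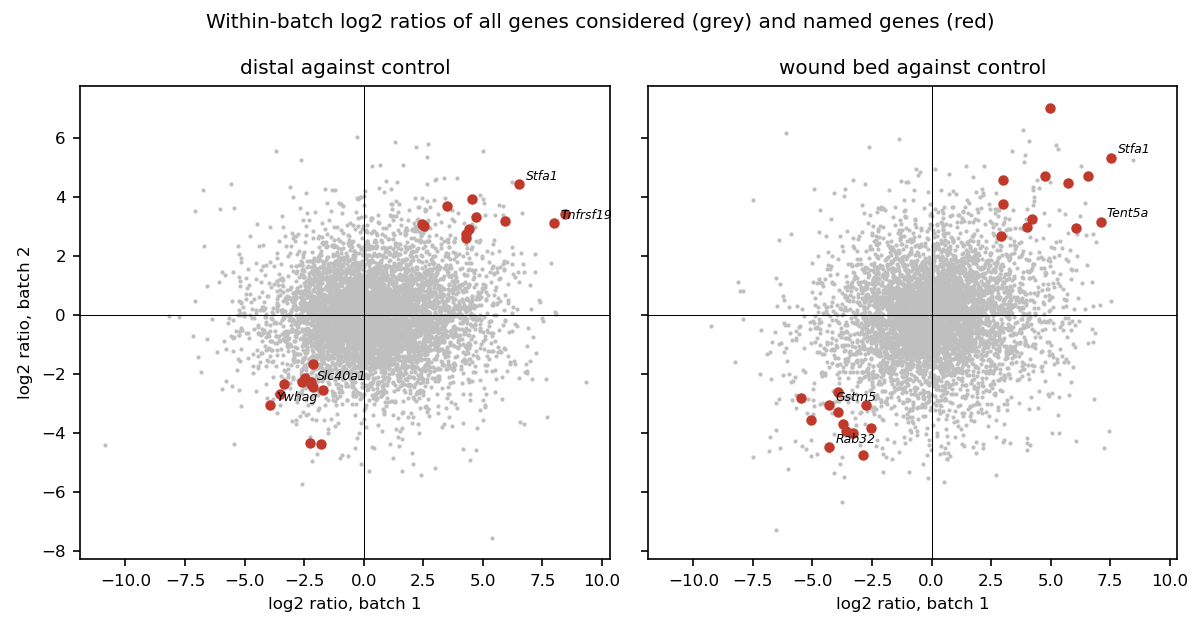
Each point is a gene, with its log2 ratio in batch 1 on the horizontal axis and in batch 2 on the vertical axis, for distal against control (left) and wound bed against control (right); red points are the genes named by rank. Ratios of all genes considered had Pearson r 0.05 on the left and 0.15 on the right.

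By the size rule, 513 genes were higher and 387 lower in distal cells of 6356 considered, where independent batches would give 443.0 and 361.9, and 842 met the size in opposite directions (820.6 by independence). In simulated cells 782 of 6573 unchanged genes met the rule. With the detection criteria of the named genes, 87 were higher and 36 lower against 56.3 and 16.9 by independence, and 127 met them in opposite directions (97.1). Across genes, Pearson r between the batches was 0.05 and Spearman rho 0.04. The share of genes meeting the rule that were higher was 57%, and 71.4% of 1156 genes without the cells rich in repeat-like reads. It was instead 47% of 2641 in batch 2 alone and 23.8% of 42 at a detection filter of 50%. Cells rich in repeat-like reads numbered 2 of 32 and 1 of 49 in the distal region. Summed over the plate, repeat-like genes still took 15.42% of non-mitochondrial reads in distal batch 2, and 0.26% in distal batch 1. In control they took 10.22% in batch 1 and 5.74% in batch 2. The upper hair follicle list no longer stood apart with every cell weighted equally, in cells with at least 2000 genes, in thinned cells, without the repeat-led cluster or without the repeat-rich cells, and within the basal epidermis-like class its median was 0.42, with batch medians of 0.3 and -0.27. Defb6 (1.68), Plet1 (0.88), Plaa (0.47) and Nfkbiz (-1.14) turned there in the mean of the batches, and Stfa3 (5.01 and 0.84), Cst6 (-0.84 and -2.11), Krt17, Erlec1, Glul, Rab32, Ywhag and Zfand6 no longer met the rule. In batch 1, 4 distal cells over 500000 reads held 72.8% of the plate's reads, and mitochondrial transcripts took 41.8% of its reads against 26.9% in control (25.9% and 23.5% in batch 2).

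Distal and wound bed cells were set against each other to ask what set the memory region at a distance apart from the wound itself. Distal cells carried more Clca3a2, 50.5-fold (6.86 and 4.46), with reads in 45.7% of distal cells (34.6 to 57.1%) and 8.2% of wound bed cells (3.4 to 16.2%), and more Ccl27a, a chemokine of keratinocytes that draws T cells, 16.7-fold (2.66 and 5.46; 51.9% and 7.1% of cells). Wound bed cells carried more Gja1, the gap junction protein connexin 43, 21.7-fold (-5.63 and -3.25 for distal against wound bed; 34.6% and 61.2% of cells), more Id1 (-3.16 and -3.76), a BMP-responsive inhibitor of transcription factors, and more Cd24a (-2.85 and -2.75), a surface glycoprotein. Of genes of antigen presentation, the class I heavy chains H2-K1 (1.71 and 3.67) and H2-D1 (1.22 and 3.13) and Tap1 (1.05 and 3.76), which carries peptides to them, met the size rule as higher in distal cells. Without the 4 cells over 500000 reads H2-K1 (0.88 and 3.67) and Tap1 (-0.25 and 3.78) no longer met it, and with every cell weighted equally none of these did.

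The interferon response and antigen presentation list had medians of 1.33 and 3.13 at percentiles 95.6 and 100, with 6 of 7 members higher in both batches, so it stood apart in batch 2 alone. Psmb8, an immunoproteasome subunit, had 3 wound bed reads in batch 1 (5.02-fold higher in distal cells, 1.64 to 25) and none in batch 2, where it was at least 36.2-fold higher in distal cells. Against control, the list was at -0.99 and -1.84 in the wound bed (percentiles 12 and 0.1), with H2-K1 at -1.88 and -2.81 and Tap1 at -1.50 and -3.70, and at -0.17 and 0.86 in distal cells. It stood apart as lower in the wound bed in cells with at least 2000 genes (-1.85 and -1.44) and without the repeat-rich cells (-2.45 and -2.32). The upper hair follicle list had medians of 1.18 and 0.36 (percentiles 98.7 and 94.9); its members Lrig1, Sostdc1 (1.11 and 1.06) and Atp6v1c2 (1.28 and 1.42) met the size rule. The list stood apart within the basal epidermis-like class (3.89 and 1.52) and without each gene's highest cell per plate (1.56 and 0.9). Of these members, Atp6v1c2 alone met the rule with every cell weighted equally, Lrig1 standing at 0.42 in batch 1 and Sostdc1 at 1.12 and 0.93, and in thinned cells none of them did. Lrig1 was at least 31.5-fold higher in distal cells in batch 2, and in batch 1 its 19 distal reads against 1 gave a 4.54-fold difference whose interval (0.722 to 189) includes equality. Ly6a was lower in distal than in wound bed cells (-2.40 and -1.61; -1.95 and -0.81 with every cell weighted equally), and Gata6 stood at 2.91 and -0.09.

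Krt15, a keratin of basal and follicle stem cells, was higher in distal than in wound bed cells (1.74 and 1.93) and lower in the wound bed than in control (-2.59 and -2.55). The basal epidermis list as a whole had medians of 0.55 and -0.16 in the first of these comparisons, 0.02 and 0.89 in the second, and 0.43 and 0.28 for distal against control. The suprabasal list had medians of -0.76 and -0.91 for distal against wound bed, with Krt1 (-2.71 and -1.24; -0.89 and -1.16 with every cell weighted equally) meeting the rule, and 0.54 and 0.06 for distal against control. The remaining genes ranked as higher in distal cells were Atf2 (3.39 and 5.87), Adgrl2 (3.17 and 3.23), Alox12e (2.85 and 3.42), Ubtf (2.99 and 2.79), Arid5b (2.73 and 2.83), Malat1 (2.69 and 3.18), Dgka (3.20 and 2.40), Aldh3a1 (2.58 and 2.40), Nagk (2.37 and 2.39) and Gstm5 (2.59 and 2.28). The remaining lower ones were Wfdc17, with 3 distal reads in batch 1 (965-fold, 329 to 4690) and -3.83 in batch 2, Slc39a6 (-3.57 and -4.39), a zinc transporter, Trim2 (-3.63 and -3.40), Cstdc5 (-2.23 and -2.29), Epha4 (-2.88 and -2.37), Ndufaf4 (-2.29 and -2.64), Adam10 (-2.25 and -2.29), Ppp2r5a (-3.12 and -1.99) and Skp1a (-1.94 and -2.61).

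By the size rule, 603 genes were higher and 332 lower in distal than in wound bed cells of 6285 considered, where independent batches would give 542.5 and 341.0, and 896 met the size in opposite directions (882.4 by independence). Among simulated genes without a difference, 724 of 6125 met the rule. With the detection criteria of the named genes, 119 were higher and 51 lower against 72.3 and 23.8 by independence, and 120 met them in opposite directions (111.9). Across genes, Pearson r between the batches was 0.05 and Spearman rho 0.02. The share of these genes that were higher, 64.5%, became 49.7% with total counts in place of TMM and 54.7% without the 4 cells over 500000 reads, 47% in thinned cells and 46.9% of 49 genes at a detection filter of 50%; the median log2 ratio of all genes was 0.25 in batch 1 and -0.02 in batch 2. Within the basal epidermis-like class Atf2 turned to -0.09, and Malat1 (0.67 and 3.59), Adam10, Dgka, Skp1a and Trim2 no longer met the rule. Without the 4 cells over 500000 reads, Malat1 (0.65), Alox12e (0.87), Arid5b (-0.05) and Ndufaf4 (-0.86) fell short of the size in batch 1, and with every cell weighted equally Alox12e, Dgka and Ubtf no longer met the rule.

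**Figure D3:**
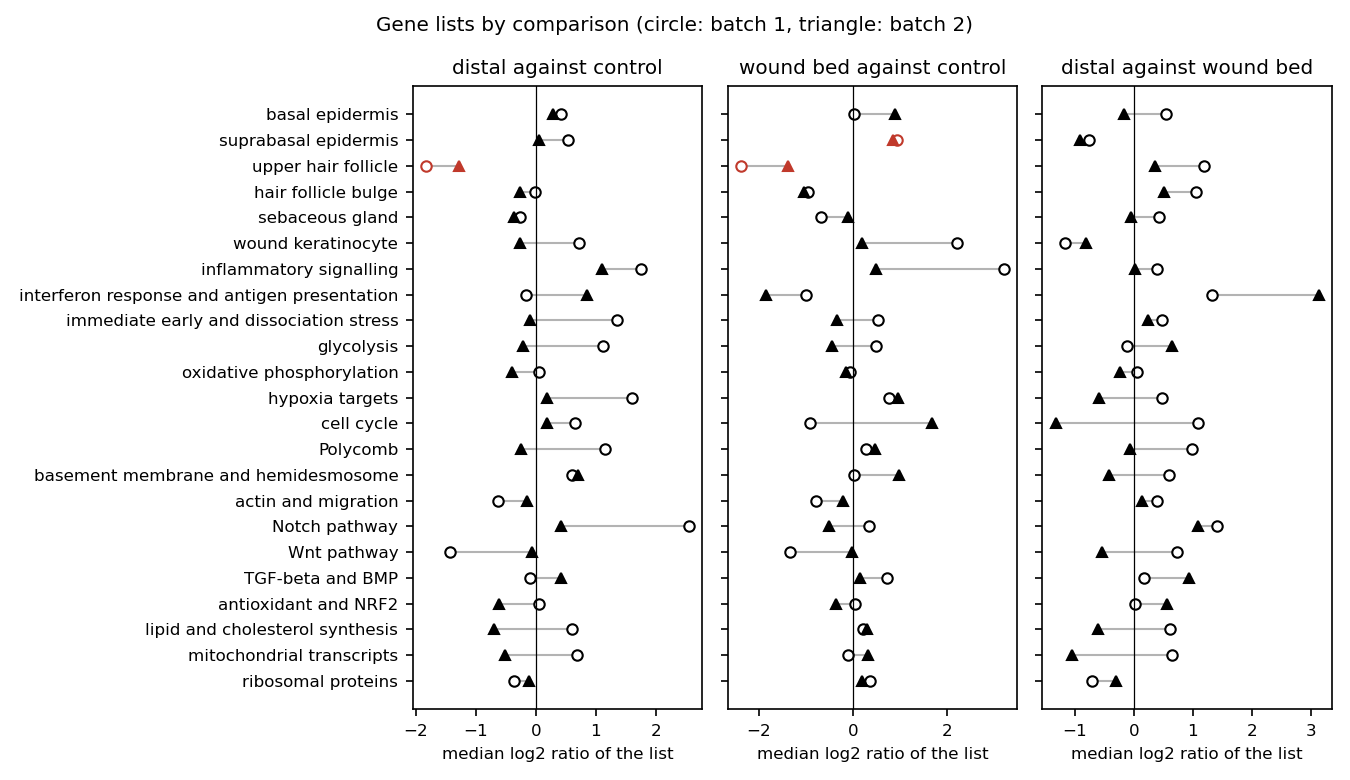
For each gene list with enough members, the median log2 ratio in batch 1 (circle) and batch 2 (triangle) is drawn on the horizontal axis for each comparison, in red where the list stood apart from random lists in both batches. The red lists are the upper hair follicle list for both regions against control and the suprabasal list for the wound bed against control.

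The 3 regions can also be put in order. Among the genes ranked for wound bed against control, distal cells lay between the other regions by scaled CPM in both batches for Stfa1, Cstdc5, Psat1, Gstm1, Gstm5 and Marcks, among others. They did not for Stfa3, Maf, Rora, Fzd7, Clca3a2 or Adgrl2. All the ranked genes were chosen for the most extreme differences between the outer regions, so that a remaining region tends to fall between them by selection. Of 5432 genes considered in both comparisons with control, 148 were in rising order from control through distal to wound bed in both batches (128.8 by independence) and 233 in falling order (179.5). Both comparisons with control share the control cells, so part of such an order follows from them.

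Clustering gave 8 groups of cells. An upper hair follicle-like cluster was led by Cst6, Krt79 and Defb6, a basal epidermis-like cluster by Igfbp4 and Krt15 among others, a cycling basal epidermis-like cluster by Top2a and Ccnb2, and a suprabasal-like cluster by Serpinb3d, Krt24 and the interferon-related Oas1f. The last was named by its marker score (1.404) and by reads of 10 suprabasal markers in enough of its cells. Its 10 leading genes held none of these markers and 1 of the hair follicle bulge, Krt24. It held 3 of 84 control cells (3.6%, interval 0.7 to 10.1%), 13 of 81 distal cells (16%, 8.8 to 25.9%) and 12 of 85 wound bed cells (14.1%, 7.5 to 23.4%). By batch it held 1 of 28 and 2 of 56 control cells, 6 of 32 and 7 of 49 distal cells, and 6 of 30 and 6 of 55 wound bed cells. Its distal and wound bed shares were each compared with control alone, since its leading gene Wfdc17 met the size rule between those regions. These are not the shares of all suprabasal-like cells. A second suprabasal-like cluster, with Krt2 and Krt10 among its leading genes, held 1 of 84 control, 7 of 81 distal and 23 of 85 wound bed cells. Sizes of that second cluster were not compared, since its leading gene Riok2 met the size rule for every pair. The cycling cluster held 6 of 84 control and 7 of 81 distal cells. The upper hair follicle-like cluster held 10 of 81 distal and 8 of 85 wound bed cells. A basal epidermis-like cluster led by Gm47585 and Malat1 held 0 of 84 control cells (interval 0.0 to 4.3%) and 1 of 85 wound bed cells (0.0 to 6.4%). For the other clusters and pairs of regions, sizes were not compared, because leading genes of the cluster were themselves among those meeting the size rule.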

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

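Alternatives with the detection filter at 50%, the detection criteria of the named genes, and without cells over 500000 reads, mitochondrial and repeat-like genes, the repeat-led cluster, the Malat1-led cluster or cells rich in repeat-like reads, and with clusters at equal weight, were chosen only after the results were seen, and the other settings were planned. The ratios pair the regions within each batch, and no test was run in any setting. A fit to the 6 plate sums with batch as a term could be made but was not run, since the labels do not say whether the batches hold different animals. For distal against control, wound bed against control and distal against wound bed in that order, the counts of genes meeting the size rule were 900, 928 and 935. They became 1496, 1719 and 1731 in cells with at least 2000 genes, 377, 562 and 494 in thinned cells, 3912, 3276 and 3344 in batch 1 alone, 2641, 2549 and 3319 in batch 2 alone, 1905, 1992 and 1987 without a detection filter, 1589, 1574 and 1606 at 1.5-fold, 42, 68 and 49 at a detection filter of 50%, and 123, 166 and 170 with the detection criteria of the named genes. Within the largest cell class, 1356 and 1439 genes met it in the first and last comparison. A single batch, no filter or a lower size passes more genes by construction; for the other settings the cause was not tested. Genes shared in the same direction were 865 of 900, 817 of 928 and 757 of 935 with total counts only, 491, 571 and 463 with the mean of per-cell CPM, 206, 308 and 218 in thinned cells, and 425, 451 and 510 within the largest cell class.

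Counting each list once per comparison, lists stood apart 14 times in batch 1 alone and 15 times in batch 2 alone, against 3 times in both. The upper hair follicle list was lower in the wound bed than in control in every setting run; the suprabasal list and the distal upper hair follicle list were not apart in some settings, as given with those results. Lists that stood apart in other settings alone, beside those given with the results, were cell cycle, lower for distal against wound bed within 3 median absolute deviations (-0.85 and -1.32), and basal epidermis, higher for wound bed against control without the repeat-led cluster (1.23 and 0.88). Thinning lowered median genes per cell to 1183 in control, 1359 in distal and 1213 in wound bed cells, since fewer reads were kept. Clusters numbered 5 at resolution 0.5 and 8 in the other clusterings.

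Directions turned as follows (log2 ratio, mean of the batches), and the cause was not tested. Within the largest cell class, distal against control gave Plaa 0.47, Defb6 1.68, Plet1 0.88, Nfkbiz -1.14, Sfrp1 0.33, Smad2 -0.92, Smad4 0.20, Sqle 2.74 and 0.42 for the upper hair follicle list; wound bed against control gave Ndrg1 0.52; and distal against wound bed gave Atf2 -0.09, Il33 0.04 and Sdha -0.11. Without cells rich in repeat-like reads, Plet1 was 0.87, Sfrp1 0.20 and Smad4 0.16 for distal against control, and Ndrg1 1.02 for wound bed against control. Within 3 median absolute deviations, Notch2 was -0.69 for distal against control and -0.61 for distal against wound bed, and Ezh1 was -0.30 in the latter. Without cells over 500000 reads, these were -0.58, -0.51 and -0.19. Ezh1 was -0.02 with the mean of per-cell CPM and -0.41 in thinned cells. In cells with at least 2000 genes, Col18a1 was 0.07 for wound bed against control. With every cell weighted equally, 22 of 24, 23 of 24 and 21 of 24 genes named by rank still met the size rule in the 3 comparisons, but only 13 of 24, 30 of 46 and 13 of 37 of the other named genes that had met it. In thinned cells 21 of 24, 24 of 24 and 23 of 24 and then 13 of 24, 34 of 46 and 13 of 37 did, and within the largest cell class 15 of 24, 22 of 24 and 18 of 24 and then 13 of 24, 27 of 46 and 19 of 37. Over 10 settings that left out cells or genes, thinned cells or weighted them equally, 11 of 24, 20 of 24 and 13 of 24 genes named by rank met the rule in each setting that held them, and 3 of 24, 11 of 46 and 6 of 37 of the others; the remaining named genes fell short in 1 or more. Those by rank were Afap1, Calml3, Fcgbp, Gga2, Lrp4, Malat1, Mettl7a1, Nxf1, Stfa1, Tnfrsf19 and Tnpo1 for distal against control. For wound bed against control they were the 24 without Ahr, Plaa, Rab32 and Tent5a. For distal against wound bed they were Adgrl2, Aldh3a1, Ccl27a, Cd24a, Clca3a2, Cstdc5, Gja1, Gstm5, Id1, Nagk, Ppp2r5a, Slc39a6 and Wfdc17. Of the other values of named genes across settings, 2199 stayed within their counting interval and 745 moved beyond it without turning; for lists, 901 stayed and 197 moved. At a detection filter of 50%, Pearson r between the batches across genes was -0.06, 0.42 and -0.03 for the 3 comparisons, against 0.05, 0.15 and 0.05 under the 10% filter.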

Other observations

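In this part, all tests were chosen only after the result was seen, except that of other nuclear long non-coding RNAs and that with the mix of clusters fixed, whose outcomes were written down before their values were looked at. Genes of other fixed lists met the size rule without their list standing apart. In the cell cycle list, Mki67 (1.56 and 1.69), Top2a (1.30 and 3.51) and Birc5 (1.97 and 1.62), all used in mitosis, were higher in the wound bed than in control, and Mcm3 (-2.39 and -2.06), part of the replicative helicase, was lower; the list's medians of -0.90 and 1.69 had opposite signs. Without the cells rich in repeat-like reads no member of the list met the size rule, and with every cell weighted equally Top2a alone did, Mki67 standing at 1.76 and 0.76 and Birc5 at 1.6 and 0.03. It was at 0.66 and 0.18 for distal against control and 1.09 and -1.32 for distal against wound bed. Among hypoxia targets, with medians of 0.77 and 0.96 in the wound bed against control, Bnip3 (1.47 and 2.48) and Higd1a (1.90 and 1.95) were higher and Ndrg1 (-1.07 and -1.61) lower, while Ndrg1 turned to 0.52 within the basal epidermis-like class. For equally weighted cells, Higd1a, Ndrg1, Hmgcs1, Wnt4 and Hspa1a were among those that no longer met the rule for wound bed against control. In distal cells, P4ha1 (2.48 and 2.29), a collagen-modifying enzyme of that list, was higher, but without the 4 deepest cells it was at 0.98 in batch 1, and no member of the list met the size rule (medians -0.02 and 0.19). In the cholesterol synthesis list, Hmgcs1 (1.01 and 1.47), Idi1 (2.53 and 3.11) and Cyp51 (1.43 and 1.97) were higher in the wound bed than in control and Sqle (-4.68 and -3.02) was lower, at list medians of 0.22 and 0.29. Of the hair follicle bulge list, at -0.96 and -1.04, Sox9 (-3.78 and -1.02) was lower and Lhx2, a transcription factor of follicle stem cells, had no wound bed read in either batch, at least 7.69-fold and 89-fold lower than in control. Col18a1 of the same list had 3 wound bed reads in batch 1 (6.15-fold lower, interval 1.94 to 31.2) and -1.05 in batch 2, and Mt2 (2.44 and 1.7), a basal-list metallothionein, was higher in the wound bed.

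In the TGF-beta and BMP list, at -0.09 and 0.42 for distal against control, Id1 (-2.86 and -3.57) and Bmp7 (-2.16 and -1.40) were lower in distal cells, and Skil had 2 control reads in batch 1 (ratio 268, interval 73.9 to 2210) and 2.12 in batch 2. Notch1 (2.26 and 1.44) was higher in distal cells than in control, with list medians of 2.56 and 0.43, and Notch2 turned to -0.58 without the 4 deepest cells. In the Wnt list, at -1.34 and -0.01 in the wound bed, Wnt4 (-1.28 and -1.61) was lower beside Fzd7. Medians for wound bed against control were -0.67 and -0.11 for sebaceous gland, 0.54 and -0.33 for immediate early genes, 0.50 and -0.45 for glycolysis, -0.07 and -0.15 for oxidative phosphorylation, 0.27 and 0.47 for Polycomb, 0.02 and 0.99 for basement membrane, -0.79 and -0.20 for actin and migration, 0.05 and -0.36 for antioxidant genes, -0.10 and 0.33 for mitochondrial transcripts and 0.37 and 0.19 for ribosomal proteins. For lists of other cell types, 0 of 250 cells had reads of 3 or more markers of fibroblasts, myeloid cells, melanocytes, endothelium or Merkel cells, and 1 distal cell had them for T cells. The single fibroblast marker considered, Sparc, which keratinocytes also express, was at 2.88 and 2.38 in the wound bed against control. The median of mitochondrial transcripts for distal against control, 0.69 in batch 1, became 0.61 with genes without reads at their bound.

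Other members of fixed lists met the size rule as well. For distal against control, Cdh3 (1.57 and 2.24), Jun (1.96 and 1.14), Plec (2.4 and 1.23), Ndrg1 (1.6 and 1.8), Idi1 (4.16 and 2.01), mt-Rnr2 (1.11 and 1.11), Smad2 (2.61 and 1.08) and Notch2 (2.85 and 1.19) were higher. Thbs1 (-1.3 and -1.64), Sqle (-4.04 and -2.81), Sfrp1 (-4.11 and -1.18) and Smad4 (-1.92 and -1.64) were lower. Hspa1a, a heat shock gene, had 3 control reads in batch 1 (13.5-fold higher in distal cells, 4.48 to 66.8) and 1.72 in batch 2, and Ddit4 had 3 distal reads in batch 1 (5-fold lower, 1.14 to 30) and none in batch 2 (at least 2.12-fold lower). Bmp7, Jun, Plec, Ndrg1, Ddit4, Sfrp1, Smad2, Smad4 and mt-Rnr2 no longer met the rule for distal against control with every cell weighted equally. Without the 4 deepest cells, Ddit4, Ndrg1, Notch2, Thbs1 and mt-Rnr2 did not. Within the basal epidermis-like class, Smad2 turned to -0.92, Smad4 to 0.20, Sfrp1 to 0.33 and Sqle to 2.74. For wound bed against control, Fos (3.24 and 1.43), Rps3a3 (1.16 and 1.29) and the mitochondrial tRNAs mt-Tq (2.42 and 1.66), mt-Ta (2.84 and 3.55), mt-Tc (3.51 and 2.23) and mt-Tn (at least 21.5-fold in batch 1, 4.36 in batch 2) were higher. So were Hspa1a (37.1-fold in batch 1, 12.1 to 185, and 1.5 in batch 2), Col7a1 (6.5-fold, 1.67 to 36.8, and 2.19) and Jarid2 (at least 22.8-fold, and 1.19), while Ndufb8 (-1.76 and -1.4), Ndufv1 (-1.48 and -1.16), Actg1 (-1.57 and -1.24) and Gpx4 (-2.89 and -1.91) were lower.

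For distal against wound bed, higher members included Dkk3 (1.06 and 1.59), Nfkbia (1.16 and 2.57), Jun (1.76 and 1.89), Ier2 (1.04 and 1.01), Hk1 (2.28 and 1.22), Sdha (2.15 and 1.14), Cyc1 (1.45 and 1.11), P4ha1 (2.18 and 2.1), Ndrg1 (2.67 and 3.41), Ezh1 (1.39 and 1.19), Notch2 (2.11 and 2.08), Fzd7 (1.93 and 4.28), Tgfbr1 (4.11 and 2.53), Skil (3.88 and 1.27) and Gstm1 (1.86 and 3.05). Ezh1 and Notch2 turned without the 4 deepest cells (-0.19 and -0.51), where Ndrg1 (0.77 in batch 1), Fzd6, Fzd7, Hk1, Ier2, Nfkbia, P4ha1, Sdha and mt-Tn no longer met the rule, and Sdha within the basal epidermis-like class (-0.11). With few wound bed reads in batch 1, Pfkl (14.9-fold, 4.05 to 125, then 9.68-fold, 3.02 to 49.5, in batch 2), Gclc (14.9-fold, 4.05 to 125, then a log2 ratio of 1.33), Bap1 (22.9-fold, 4.02 to 916, then 1.13) and Vcl (53.3-fold, 9.47 to 2110, then at least 21.2-fold) were higher too. The lower members were Il33 (-3.15 and -1.44), Egln3 (-1.7 and -1.47), Fzd6 (-1.22 and -1.33), Wls (-1.3 and -1.92), Sfrp1 (-4.22 and -1.38), mt-Ta (-2.0 and -3.71) and mt-Tn (-1.95 and -2.78). Il33 was at 0.04 within the basal epidermis-like class. With every cell weighted equally, Bap1, Dkk3, Ezh1, Fzd6, Fzd7, Gclc, Hk1, Ier2, Il33, Nfkbia, Notch2, P4ha1, Sdha, Sfrp1, Tgfbr1 and mt-Tn no longer met the rule for distal against wound bed.

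The 24 genes named by rank for wound bed against control had a median log2 ratio, signed by direction, of 4.10 and 3.73. Within the basal epidermis-like class the lower of the batch medians was 3.74, but the class compares different clusters, since 35 of its 41 control cells fell in 1 cluster and 26 of its 42 wound bed cells in another without control cells. The mix was then fixed at equal weights of the 3 clusters with at least 2 cells of both regions in each batch. These held 62 control and 23 wound bed cells. The lowest median over the 12 higher or 12 lower genes in a batch was 1.92. That met the outcome written down beforehand against a different mix of cells as the whole cause. Of the 24 genes 21 kept their direction in both batches, while Ahr turned in both and Rab32 and Plaa in batch 1. None of the 3 clusters was suprabasal-like, and the one led by Igfbp4 held only 2 wound bed cells in each batch. The test argues against the mix as the whole cause for the few cells it covers alone. Medians of 2.27 and 2.65 leave room for the mix as part of it. Without the cells rich in repeat-like reads the lower batch median was 3.67, which argues against those cells as the whole cause for these genes. In thinned cells it was 3.49, but thinning leaves the expected CPM of a cell unchanged, so a difference in depth is not decided. The 24 genes were ranked for large differences in these same cells, which favours high medians in each such subset. A change of state of wound bed cells may underlie these genes, as a hypothesis. Sequencing depth, the animal, the plate, selection by the Ly6a sort and finer cell states within the class stay open. So do reads shared between paralogs for the stefin A and Gstm families.

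The upper hair follicle list was lower in both regions than in control, and fewer upper hair follicle-like cells cannot be told apart from fewer reads within cells in either region. For the distal region, the list's median within the basal epidermis-like class was 0.42, but its batch medians of 0.3 and -0.27 and its members, 3 higher and 4 lower in both batches, went both ways. For the wound bed it was -1.81, with -2.75 in batch 1 and only -0.62 in batch 2. The class does not hold the mix of cells fixed, since 35 of its 41 control cells but 12 of 48 distal cells fell in a cluster with reads of 8 upper hair follicle markers, and 26 of 42 wound bed cells in a cluster with 2. Selection by the Ly6a sort, the place of sampling, the plate and the animal stay open for both.

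Malat1 was higher in distal cells than in control cells by 4.55 and 3.94. The 4 deepest distal cells are argued against as the whole cause by a log2 ratio of 2.5 in batch 1 without them, although they may account for much of the batch 1 value. The cluster led by Malat1 and Gm47585 held 18 of 81 distal cells, 3 of 32 in batch 1 and 15 of 49 in batch 2. It is argued against as the whole cause by a lower batch value of 3.12 without it. A larger nuclear share of the RNA in distal cells cannot be told apart from a change in Malat1 itself. A first test used ribosomal protein genes, whose higher batch median was -0.12, which went against that explanation, but scaling holds the medians of such abundant genes near 0, so it was replaced after its result was seen. In the test that replaced it the other nuclear RNAs had a lower batch median of 4.44. This met the outcome written down beforehand for a larger nuclear share. It rests on 3 genes that did not move together (Neat1 at 4.49 and 1.78, Kcnq1ot1 at 6.22 and 4.53, Ftx at -5.59 and 4.44), which may be too few to decide. The plate and the animal stay open for Malat1 as well.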
